A study of Mus musculus with 8 samples.

How the data were processed

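Gene expression was measured on 8 Affymetrix mouse expression arrays, hybridised with biotin-labelled total RNA from tumour-associated macrophages. Per the labels, the cells were sorted from tumour-bearing mice 4 weeks after implantation, as CD45.2-positive, CD19-negative cells positive for CD11b, CD115 and F4/80. The groups were 4 wild-type (WT) samples and 4 samples lacking p110δ (p110d-/-), the catalytic PI3K subunit encoded by Pik3cd, and the sample titles gave each sample its group and number. The series design speaks of chimeric mice. The titles of the 4 p110d-/- samples hold the word chimeric, and those of the 4 WT samples do not. Whether the WT samples also came from chimeras is not given in the sources used here. If the WT samples did not, genotype and chimerism cannot be told apart. No label states that each sample came from a separate mouse, so the p-values measure the spread between these samples, which may be partly technical.

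The deposited table holds a value per probe set and array, taken here as log2 signal because the values have the range of summarised log2 Affymetrix data. The scale is not stated, and neither the summarisation nor the normalization method is given in the sources used here. The distributions of the 8 columns lie close together, so the deposited log2 values were treated as already normalized between arrays by the authors. Genes were not centred. The array medians were 5.53, 5.55, 5.52 and 5.53 for WT 1 to 4 and 5.49, 5.49, 5.49 and 5.48 for p110d-/- 1 to 4. Scanner files were not used here, so no probe has a measured background, and the number of arrays limits the precision.

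Probe sets were named from the platform's annotation table, with symbols updated through Entrez identifiers in a mouse gene table of assembly GRCm38.p6. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none here. A probe set without a name here was not named in any other way, and genes left without a named probe set, Cd19 among them, are not analysed here. For statements on genes, each of 18193 genes was represented by its probe set of highest mean signal over the 8 arrays. The gene table served for names, for the order of genes along a chromosome and for their genomic span. None of its coordinates are given, because the array annotation names no genome build.

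Differences (p110d-/- minus WT) were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes without a trend). The test was two-sided, with Benjamini-Hochberg adjustment over all 45101 probe sets and a threshold of 0.05. Adjusted p-values of single genes come from that fit, unless the text names another fit or an adjustment over a list alone. A two-sided exact permutation test over the 70 assignments of 4 and 4 samples was used for single measures, and 0.0286 is the smallest p it can give. Of 37 gene lists, 36 had at least 3 measured members. These were tested with limma's camera at a preset correlation of 0.01, adjusted over the 36 lists, on the representative probe sets.

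The gene lists and the rule for the genes to be named were fixed before the data were examined. The genes named are the class I PI3K subunits, the sort markers, and up to 12 genes per direction with the largest change among those past the threshold. Where fewer passed, the list was filled by smallest unadjusted p among genes whose groups did not overlap and whose fold was at least 1.5. Up to 4 members of each list with the smallest p were added. Predicted gene models, olfactory and vomeronasal receptors were skipped.

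The fit was tested on simulated data with 45101 probe sets and 200 changed ones. It recovered 77.6% of the 1.5-fold changes, 94.0% of the 2-fold and 98.5% of the 4-fold changes, and 15 of the 195 probe sets called were unchanged ones. The simulated noise was normal and independent between probe sets, with the observed SDs moved toward their median. Correlation between genes and differences between arrays were not simulated, so these rates need not hold for the real arrays. Alternatives covered the replicate number as a block, quantile normalization, median centring, a filter on dim probe sets, array weights, each sample left out in turn, a mean-variance trend, ordinary t statistics, and other treatments of probe sets and lists. Cyclic loess, removal of a trend with genomic span, and omission of control probe sets or of the genes beside Pik3cd were chosen after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.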

Results

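Tumour-associated macrophages from 4 WT and 4 p110d-/- samples were compared to ask how loss of p110δ, the PI3K catalytic subunit typical of leukocytes, alters macrophage gene expression in tumours. All 8 samples were collected 4 weeks after tumour implantation. Pearson correlations between arrays, taken across probe sets, lay between 0.983 and 0.995, and no 2 arrays were duplicates. Xist, the X-inactivation transcript, was high in both groups (log2 12.47 ± 0.24 in WT and 12.50 ± 0.51 in p110d-/-, SD, n = 4).

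Pik3cd, the targeted gene, was measured by 6 probe sets that did not move together. The brightest read 12.22 ± 0.22 in WT and 11.77 ± 0.15 in p110d-/- samples (SD, n = 4). Its log2 difference was -0.45 (SE 0.12), lower in 4 of 4 p110d-/- samples, with an exact permutation p of 0.0286, the smallest possible. It did not pass limma's test over all probe sets (adjusted p = 0.20). A dimmer probe set went the other way, from 6.57 ± 0.34 to 8.47 ± 0.55, a log2 difference of 1.90 (adjusted p = 0.0547). The mean over all 6 probe sets was 0.21 higher in p110d-/- samples (adjusted p = 0.257), opposite in sign to the brightest probe set. The labels do not say which part of the gene was deleted, and a probe set outside that part does not check the genotype.

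**Figure D1:**
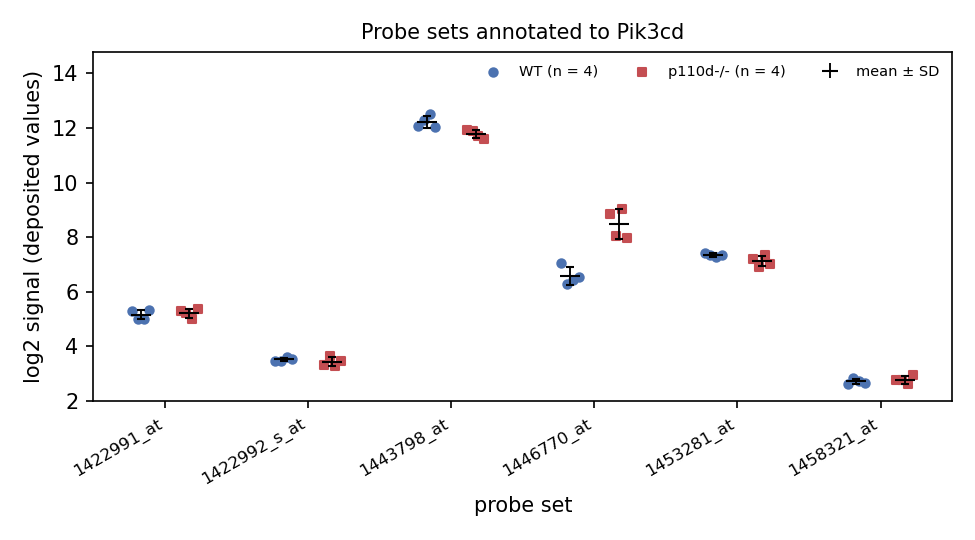
Deposited log2 signal (vertical axis) of the 6 Pik3cd probe sets (horizontal axis) in 4 WT (circles) and 4 p110d-/- samples (squares), with mean ± SD in black. The p110d-/- samples lie below WT for the brightest probe set (difference -0.45) and above WT for a dimmer one (difference 1.90).

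The largest decrease among named genes in p110d-/- macrophages was in Car6, a secreted carbonic anhydrase, from 10.63 ± 0.48 in WT to 6.70 ± 0.41 (SD, n = 4), 15.2-fold lower (log2 -3.93, SE 0.26; adjusted p = 0.00174). Rab6b, a small GTPase of the Golgi, was 4.32-fold lower (log2 -2.11, SE 0.15; adjusted p = 0.0021). Fblim1, a filamin-binding LIM protein of cell adhesions, was 4.31-fold lower (log2 -2.11, SE 0.15; adjusted p = 0.0021). Efhd2, a calcium-binding regulator of actin, fell from 13.18 ± 0.13 to 11.42 ± 0.47, a 3.39-fold difference (adjusted p = 0.0237). The zinc-finger gene Zfp991 (2.64-fold, adjusted p = 0.0132), the pseudogene Znf41-ps (1.92-fold, adjusted p = 0.0288) and Scrn2 (1.67-fold, adjusted p = 0.029) were also lower.

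The largest increase among named genes was in Slc15a2, a proton-coupled peptide transporter, from 6.73 ± 0.55 in WT to 10.08 ± 0.42 in p110d-/- (SD, n = 4), 10.2-fold higher (log2 3.35, SE 0.28; adjusted p = 0.00471). Wdfy1, a FYVE-domain protein of endosomes, rose 3.92-fold (log2 1.97, SE 0.17; adjusted p = 0.00471). Clstn1, a membrane protein linked to vesicle transport, rose 2.49-fold (log2 1.32, SE 0.13; adjusted p = 0.00722). Cyp7b1, an oxysterol hydroxylase, rose 2.11-fold (adjusted p = 0.0489), Rab4a, a GTPase of endosome recycling, 1.82-fold (adjusted p = 0.0366), and Nrm, a nuclear envelope protein, 1.59-fold (adjusted p = 0.0342). In each of these 13 genes the 4 p110d-/- values all lay on one side of the 4 WT values.

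**Figure D2:**
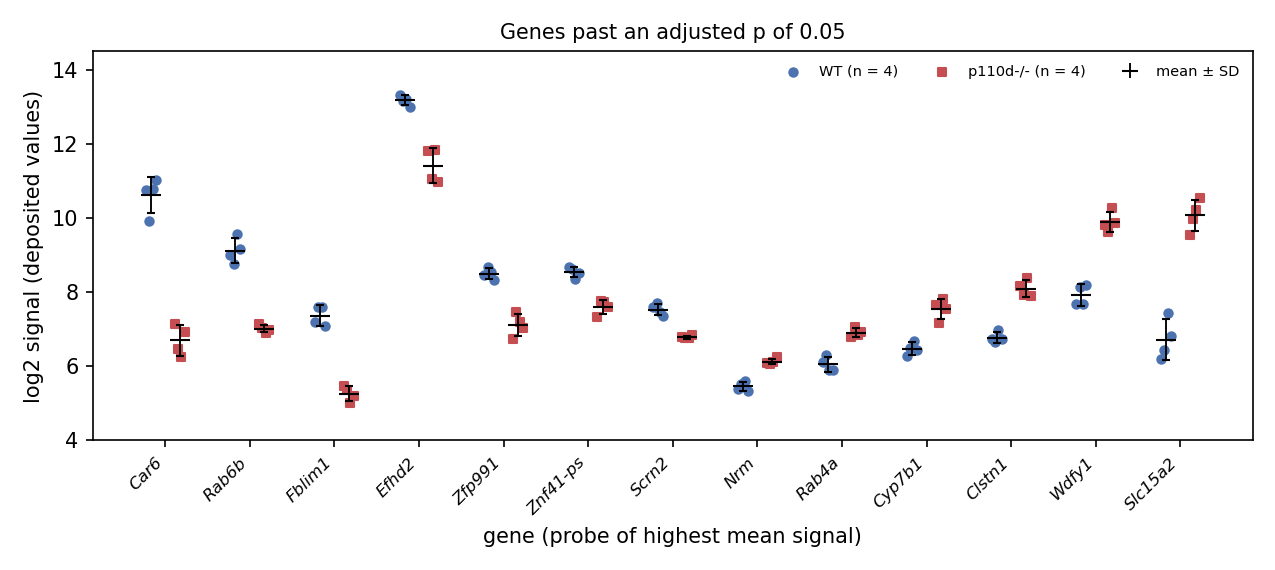
Deposited log2 signal (vertical axis) of the 13 genes past an adjusted p of 0.05 (horizontal axis, ordered by change), by the probe set of highest mean, in 4 WT (circles) and 4 p110d-/- samples (squares), with mean ± SD in black. The groups do not overlap for any of the 13 genes, from Car6 (log2 -3.93) to Slc15a2 (log2 3.35).

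In total 37 of 45101 probe sets passed, 19 higher and 18 lower in p110d-/-, and they named 20 genes, 13 of them by the gene's brightest probe set. Of the 37, 11 had no single gene name, among them the probe sets with 11.4-fold and 8.57-fold higher signal. The 8.57-fold one is annotated to Rex2, Zfp980 and Zfp600. Rex2 and Zfp980 lie at positions -39 and -43 from Pik3cd in gene order, though probe sets of either gene alone did not pass. The shared probe set is not in the count of neighbours below, and it was kept where the genes beside Pik3cd were left out. At an unadjusted p under 0.05 there were 6996 probe sets (3090 higher, 3906 lower), against 2255 expected by chance. Other splits of the samples into 4 and 4 gave 790 to 4781 such probe sets. Counts above 2255 thus also arose without the real grouping, though some of those splits kept most of it. The groups did not overlap for 9.34% of probe sets, where chance gives 2.86%. Probe sets of the same gene often differed. Zfp991 fell by 1.40 on its brightest probe set but was 1.24 higher on another, both past the threshold. Efhd2 was 0.90 lower on its other probe set, short of the threshold (adjusted p = 0.119). Slc15a2 passed on 1 of 3 probe sets, Clstn1 on 1 of 2 and Wdfy1 on 3 of 5, while Rab6b passed on 3 of 4 and Fblim1 on 2 of 2. Another Wdfy1 probe set differed by -0.37 (adjusted p = 0.148). Of the 20 genes, 6 lie on chromosome 4 among the 300 measured genes up to 200 positions from Pik3cd in the gene order of GRCm38.p6, namely Car6, Clstn1, Zfp991, Znf41-ps, Efhd2 and Fblim1. That is 2.0% of these neighbours, against 14 of 17730 genes elsewhere (0.079%; odds ratio 25.8, two-sided Fisher's exact p = 6.43e-07). The windows were chosen after the values were seen, and the odds ratio was 19.1 to 46.6 with windows of 300 to 50 genes each side.

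Car6, Rab6b, Fblim1, Slc15a2, Clstn1 and Wdfy1 passed whichever sample was left out. Zfp991 lost the call without WT 1 (adjusted p = 0.051), WT 2 (0.0738) or p110d-/- 4 (0.0822), and Efhd2 without WT 1 (0.0838), WT 2 (0.0953), WT 4 (0.0937), p110d-/- 2 (0.0768) or p110d-/- 4 (0.0796). Rab4a kept its call only without WT 2 (adjusted p = 0.0392, up to 0.159 without another sample). Nrm and Znf41-ps kept theirs only without WT 3 (both 0.0455, otherwise up to 0.152 and 0.146). Scrn2 did so only without WT 3 (0.0472) or WT 4 (0.0417), otherwise up to 0.131, and Cyp7b1 only without WT 3 (0.0472) or p110d-/- 2 (0.0244), otherwise up to 0.196. The number of probe sets called was 16, 16, 59 and 17 without WT 1, 2, 3 and 4, and 21, 20, 17 and 15 without p110d-/- 1, 2, 3 and 4. Ordinary t statistics in place of limma's moderated ones gave 4 calls, 1 of them shared, and 23 remained when the genes beside Pik3cd were left out.

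**Figure D3:**
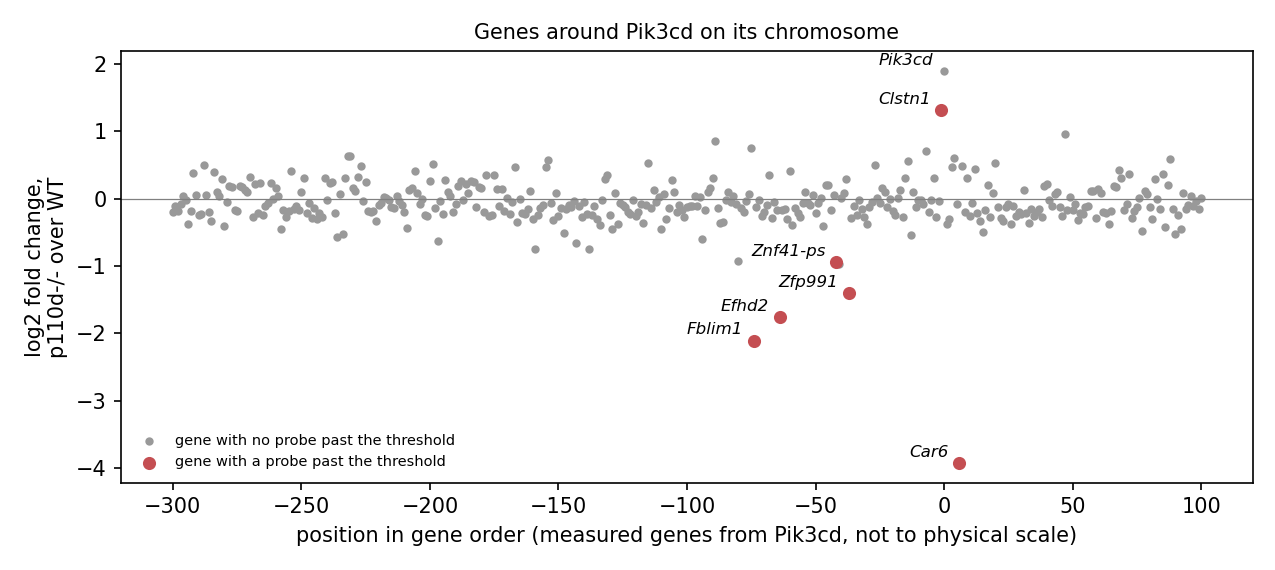
Log2 fold change, p110d-/- over WT (vertical axis), of measured genes around Pik3cd in their order along the chromosome (horizontal axis, genes from Pik3cd, not to physical scale), each by its probe set with the largest test statistic. Red points are the 6 genes past the threshold, from Fblim1 at position -74 to Car6 at position 6, and Clstn1 is the adjacent gene at position -1.

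Among genes that did not pass but whose groups were separate, Mid1, a microtubule-associated ubiquitin ligase, had a log2 difference of 1.46 (SE 0.24; adjusted p = 0.0994). Klhl42 (0.73), Zfp518b (0.70), Csrnp2 (0.68), Atxn7l1 (0.68) and Ly75 (0.62), an endocytic receptor of dendritic cells, were the others on the higher side, with adjusted p from 0.0697 to 0.103. On the lower side Minar1 differed by -1.09 (SE 0.18; adjusted p = 0.0994), Tcp11x2 by -0.76, Svs5 by -0.72, Ifi27l2b by -0.68 and Padi3 by -0.60, with adjusted p from 0.0547 to 0.119. Minar1 passed without WT 2 (adjusted p = 0.0195), Mid1 without p110d-/- 1 (0.0423) and Ifi27l2b without WT 3 (0.0455).

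The other class I PI3K subunits did not pass. The catalytic genes Pik3ca (log2 difference 0.54, SE 0.17, adjusted p = 0.238), Pik3cg (0.55, SE 0.20, adjusted p = 0.269) and Pik3cb (0.35, SE 0.15, adjusted p = 0.30) had positive differences. The p110γ adaptor genes Pik3r5 (0.59, adjusted p = 0.221) and Pik3r6 (0.41, adjusted p = 0.177) did too, and the groups did not overlap for Pik3ca, Pik3r5 and Pik3r6. Pik3r1 differed by 0.25, Pik3r3 by 0.27 and Pik3r2 by -0.11. The sort markers did not pass either. Csf1r, encoding CD115, differed by 0.07, Adgre1, encoding F4/80, by 0.08, Ptprc, encoding CD45, by 0.10 and Itgam, encoding CD11b, by 0.49 (SE 0.21, adjusted p = 0.302). Cd19 was not analysed here.

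Of 36 gene lists tested, camera with the preset correlation put 5 past the threshold, and 0 passed with an estimated correlation or with fry. At an unadjusted p under 0.05 the counts were 13, 1 and 11. Ribosomal protein genes were lower in p110d-/- for 25 of 29 members (mean log2 difference -0.20; camera adjusted p = 0.00031; adjusted p = 0.634 with an estimated correlation). Rps10 differed by -0.61, Rps24 by -0.48, Rps9 by -0.46 and Rps14 by -0.38. In limma, 0 members passed over all genes and 1 (Rps9) adjusted over the list alone, while 1 was higher and 10 lower at an unadjusted p under 0.05. Oxidative phosphorylation genes were lower for 27 of 33 members (mean -0.17; camera adjusted p = 0.00671; adjusted p = 0.769 with an estimated correlation). They were led by Ndufa2 (-0.60), Cycs (-0.54), Ndufb8 (-0.48) and Cox6c (-0.47). In this list 0 members passed in limma over all genes and 1 (Cox6c) adjusted over the list alone, with 9 lower at an unadjusted p under 0.05. PI3K signalling genes were higher for 28 of 35 members (mean 0.17; camera adjusted p = 0.00309; adjusted p = 0.579 with an estimated correlation), and 0 passed in limma over all genes or adjusted over the list alone, with 8 higher and 1 lower at an unadjusted p under 0.05. The list means of WT 3 for ribosomal proteins (-0.12) and oxidative phosphorylation (-0.13) lay among the p110d-/- values. Among bright genes the deviation of WT 3 from the 8-array mean was also positively related to genomic span (Spearman rho across genes 0.234), as in the p110d-/- samples (0.0644 to 0.232) and unlike WT 1, 2 and 4 (-0.30, -0.296 and -0.12), and its 18S rRNA signal of 11.17 was the highest of the WT samples. The exact permutation p of the list means was 0.114 for ribosomal proteins, 0.0857 for oxidative phosphorylation and 0.0286 for PI3K signalling, whose groups did not overlap.

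Markers of other cell types were also compared. T cell genes were lower for 15 of 17 members (mean -0.20; camera adjusted p = 0.0329; adjusted p = 0.579 with an estimated correlation), among them Cd3d (-0.34), Cd8b1 (-0.25), Zap70 (-0.23) and Cd8a (-0.16). WT 4 held the highest T cell mean, 0.39 against -0.05 to 0.03 in the other WT samples. The call was lost without WT 4 (mean -0.10, adjusted p = 0.18), WT 3 (adjusted p = 0.0749) or p110d-/- 1 (adjusted p = 0.0762). B and plasma cell genes were lower for 14 of 16 members (mean -0.25; camera adjusted p = 0.046; adjusted p = 0.579 with an estimated correlation), among them Jchain (-1.78, SE 0.63), Cd22 (-0.29), Cr2 (-0.23) and Ebf1 (-0.18). The mean rested in part on Jchain, and it was -0.14 over the other 15 members. That call was lost without WT 1 (adjusted p = 0.0574), WT 3 (0.143), p110d-/- 1 (0.0762) or p110d-/- 4 (0.0856). In limma, 0 genes of either list passed over all genes or adjusted over the list alone, and 5 T cell and 4 B and plasma cell genes were lower at an unadjusted p under 0.05.

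**Figure D4:**
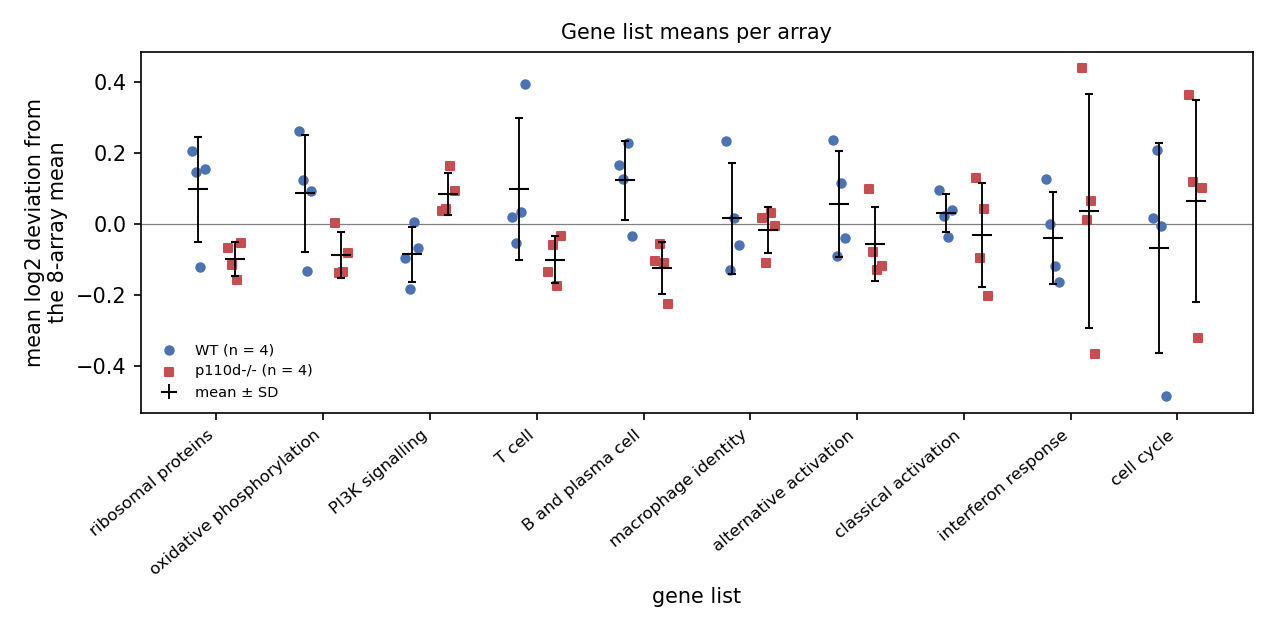
Mean log2 deviation from the 8-array mean (vertical axis) over the members of 10 gene lists (horizontal axis) in 4 WT (circles) and 4 p110d-/- samples (squares), with mean ± SD in black. Ribosomal protein means are 0.10 ± 0.15 in WT and -0.10 ± 0.05 in p110d-/-, with WT 3 at -0.12.

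The macrophage activation lists did not pass. Of 27 alternative activation genes 7 had positive and 20 negative differences (camera adjusted p = 0.31): Arg1, the arginase of alternatively activated macrophages, differed by -0.70 (SE 0.23, adjusted p = 0.243) and the scavenger receptor gene Stab1 by -0.48, while Chil3 (1.11, SE 0.39, adjusted p = 0.257) and Cd163 (0.67) were on the higher side. Of 31 classical activation genes 15 were positive and 16 negative (camera adjusted p = 0.625). The cytokine gene Il1a differed by -0.76 (SE 0.14; adjusted p = 0.14) and passed adjusted over the list alone (0.0115) or, over all genes, without p110d-/- 1 (0.045). Ccl2 differed by -0.50, Fpr2 by 0.45 and Slamf1 by -0.32. Of 33 chemokine and receptor genes 23 were negative (camera adjusted p = 0.104), with Cxcr2 at -0.31 and Pf4 at -0.33, and the list passed under median centring at the preset correlation (adjusted p = 0.0376; adjusted p = 0.634 with an estimated correlation on the deposited values). Macrophage identity genes were split 12 to 12 (camera adjusted p = 0.885), C1qb at -0.51 and Cd14 at 0.30. Of 17 monocyte genes 8 were positive and 9 negative, with a median of -0.04 and a mean of 0.07 (camera adjusted p = 0.59), Hp at 0.48 and Nr4a1 at -0.35. The mean was -0.06 without p110d-/- 3, whose own value was 0.41.

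Interferon response genes were positive for 24 of 35 members (camera adjusted p = 0.104), with Oasl2 at 0.54 and Ifi204 at -0.38, but the list's direction rested on single samples. The mean of 0.08 became -0.06 without p110d-/- 1 (adjusted p = 0.718), while the list passed, at the preset correlation (0.834 with an estimated correlation and all samples), without WT 1 (0.0389) or p110d-/- 4 (8.26e-05); the p110d-/- 1 and p110d-/- 4 means were 0.44 and -0.37. MHC class II genes were negative for 11 of 16 (adjusted p = 0.59; H2-Aa -0.46, Rfx5 0.48) and MHC class I genes positive for 11 of 16 (adjusted p = 0.476; Erap1 0.38), and these means changed sign without p110d-/- 4 (0.04) and without p110d-/- 1 (-0.04). Cell cycle genes were positive for 31 of 39 members (adjusted p = 0.104; Bub1 0.43, Ccne2 0.45) with a mean of 0.13. They passed at the preset correlation without WT 1 (0.0389), WT 2 (0.00362) or p110d-/- 3 (0.000467), against an adjusted p = 0.834 with an estimated correlation and all samples, but the mean was -0.01 without WT 4 (adjusted p = 0.986) and 0.03 without p110d-/- 1 (0.705). Angiogenesis and matrix genes were negative for 22 of 36 (adjusted p = 0.476; Col14a1 -0.95, Pdgfc -0.90), and checkpoint genes were split 12 to 12 (adjusted p = 0.824; Tnfsf4 -0.36, Tnfsf9 0.42). Hypoxia and glycolysis genes were negative for 18 of 29 (adjusted p = 0.828; Pfkp 0.41). Among metabolic lists, cholesterol and fatty acid synthesis was negative for 16 of 25 (adjusted p = 0.815), although Elovl6, a fatty acid elongase, differed by 0.71 and passed adjusted over the list alone (0.0212). Lipid handling was negative for 14 of 24 (adjusted p = 0.594; Plin2 0.65, Abca1 0.41) and lysosome positive for 18 of 30 (adjusted p = 0.59). In the unfolded protein list, 16 of 26 negative (adjusted p = 0.59), Ern1 (0.55) and Atf4 (-0.43) both passed adjusted over the list alone. FOXO target genes were positive for 13 of 23 (adjusted p = 0.545; Insr 0.38, Il7r -0.76), and immediate early genes for 15 of 22 (adjusted p = 0.501; Dnajb1 0.46). The list of Pik3cd neighbours was positive for 24 of 44 (adjusted p = 0.545). Clstn1 passed over all genes. Adjusted over the list alone, 4 were higher (Clstn1, Clcn6 at 0.50, H6pd at 0.60 and Rere at 0.49) and 2 lower (Casz1 at -0.32 and Pik3cd itself at -0.45). The mean shift of the FOXO target, checkpoint, cholesterol, lipid handling, unfolded protein, macrophage identity, lysosome, NK cell and Y-linked lists changed sign under median centring, quantile normalization or cyclic loess, and all of these but the unfolded protein and NK cell lists also did so without some single sample.

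Lists of other cell types were mostly on the lower side without passing: erythroid 8 of 9 negative (camera adjusted p = 0.0689), exocrine pancreas 9 of 11 (0.113), fibroblast 15 of 21 (0.113), platelet 9 of 11 (0.117), eosinophil, mast cell and basophil 15 of 17 (0.132), dendritic cell 14 of 18 (0.278), epithelial 14 of 19 (0.388), endothelial 9 of 17 (0.463) and NK cell 7 of 13 (0.545). Lists of random genes matched on signal also had negative medians, from -0.07 for the NK cell to -0.03 for the dendritic cell list. The median lay at percentile 0.35 of these for dendritic cell and 2.35 for erythroid genes, but at 6.5 for fibroblast, 7.1 for platelet, 12.65 for exocrine pancreas, 12.95 for epithelial, 21.4 for eosinophil, 44.35 for NK cell and 69.4 for endothelial genes. Neutrophil genes were positive for 10 of 16 (0.347; Cd177 0.64), with a mean of 0.13 that was -0.02 without p110d-/- 3 and a median at percentile 99.5, melanocyte genes for 6 of 11 (0.824, percentile 96.6) and Y-linked genes for 4 of 5 (0.885, percentile 92.65), with Eif2s3y at 3.05 ± 0.08 in WT and 3.12 ± 0.14 in p110d-/-. Adjusted over the list alone, the dim Ly75 (3.09 in WT and 3.71 in p110d-/-) of the dendritic cell list was higher. Col5a1 (-0.35) and Pdgfrb (-0.28) of the fibroblast, Cela3b (-0.27) of the exocrine pancreas and Sry (-0.39) of the Y-linked list were lower. Of these genes 0 passed the threshold over all genes in limma. The Sry probe set read 6.65 in WT and 6.26 in p110d-/-, while group means of Eif2s3y, Kdm5d and Uty lay between 3.05 and 4.13 and Xist was high. Whether that probe set measures Sry was not tested. The erythroid list passed without WT 1 (0.0423) and the fibroblast list without p110d-/- 3 (0.0428), at the preset correlation (with all samples, adjusted p = 0.579 with an estimated correlation for both). The groups' means did not overlap for 7 of the 36 lists, where chance gives 2.86%. The arrays themselves differed between groups. The median signal was 5.53 in WT (SD 0.0144, n = 4) and 5.49 in p110d-/- (SD 0.00453), and the upper quartile 7.24 and 7.34 (exact permutation p = 0.0286 for each). Across 18193 genes, which are not independent replicates, log2 fold change and mean signal had a Spearman rho of 0.313, and for genomic span rho was 0.232 over 18031 genes. The 3′ to 5′ difference of the Gapdh control was 4.57 ± 0.22 in WT and 4.54 ± 0.21 in p110d-/- (exact permutation p = 0.886). For the Actb control it was 2.99 ± 0.39 and 2.965 ± 0.16 (exact permutation p = 0.943). The 3′ probe sets thus read far brighter in both groups, and similar group values do not show that the RNA was intact. The 18S rRNA control probe set read 10.78 ± 0.40 in WT and 11.49 ± 0.12 in p110d-/- (exact permutation p = 0.0286).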

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

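The screen for samples far from the rest of their group of 4 covered 158 groups of values. Some of its items depended on results. They were genes that the naming rule picked by their values, and the Pik3cd probe set that was higher in p110d-/-. Chance marks about 1 in 20 groups, or 7.9 of these, and 2 were marked. The 7.9 is a rough guide only, since genes picked for separate groups are not a random set. In the neutrophil list, p110d-/- 3 had a mean log2 deviation of 0.50, where the other p110d-/- samples lay between -0.11 and -0.06. In the dendritic cell list, p110d-/- 1 had a mean of -0.11, where the other p110d-/- samples lay between -0.04 and -0.03. No explanation was tested for either value.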

How the results depend on the processing

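Cyclic loess, removal of the genomic span trend, and omission of control probe sets or of the genes beside Pik3cd were chosen after the results were seen. The count of 37 probe sets stayed within 1.5 times under quantile normalization (34), median centring (41), a filter on dim probe sets (37), array weights (48), trend and robust moderation (41), a minimum fold of 1.5 (36), omission of control probe sets (37) and cyclic loess (36). It was 13 with 1 probe set per gene and 23 without the genes beside Pik3cd, where fewer probe sets were tested. The called genes beside Pik3cd held only 1 or 2 called probe sets each, so the fall to 23 also took in calls on other genes. The count was 4 with ordinary t statistics, for which the cause was not tested. With a sample left out it was 15 (without p110d-/- 4) to 59 (without WT 3). With the replicate number as a block it was 17, of which 16 were among the 37. Whether the numbers pair the samples could not be told. Across probe sets, deviations of same-numbered samples correlated at 0.13, 0.11, -0.19 and 0.22. For samples of different numbers the correlations ran from -0.33 to 0.18. Under that block Wdfy1 lost its call (adjusted p = 0.0692), as did Cyp7b1, Rab4a, Nrm, Znf41-ps and Scrn2, while the chemokine list gained one at the preset correlation (0.0413; 0.634 with an estimated correlation and no block). Cyp7b1 was also short of the threshold under quantile normalization (adjusted p = 0.0687) and cyclic loess (0.0709).

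The Pik3cd difference of -0.45 lay between -0.52 and -0.36 with a sample left out and was positive only as the mean over all probe sets (0.21). The count of 5 lists was 2 under quantile normalization, 2 under cyclic loess (ribosomal proteins and oxidative phosphorylation), 0 with an estimated correlation, 0 with fry, and 3 to 7 with a sample left out (3 without WT 3 or without p110d-/- 1); the cause was not tested. PI3K signalling was short of the threshold under quantile normalization (adjusted p = 0.095), as were T cell (0.095) and B and plasma cell (0.209) genes. T cell genes were also short of it as a mean over probe sets (0.0593), and B and plasma cell genes with array weights (0.053). Calls were gained by the cell cycle list with array weights (0.013), the interferon list as a mean over probe sets (0.0302), the chemokine list with median centring (0.0376), and the exocrine pancreas (0.0454) and platelet (0.0382) lists with the filter, all at the preset correlation. On the deposited values their adjusted p with an estimated correlation was 0.834, 0.834, 0.634, 0.579 and 0.579. fry called 12 lists when either direction counted. The pseudocount alternative was not run, since the values were already on a log scale. Signal over background is unknown here, so dim probe sets could not be told from background.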

Other observations

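The neighbour odds, the list percentiles and the pair count, the use of cyclic loess and of the genomic span correction, and the permutation of list means after these corrections, were tests chosen after the results were seen. The genes of this paragraph lie outside the naming rule and were chosen after their values were seen. Of the 20 genes called, 7 passed only through a probe set other than the brightest, among them Gsdma2 (log2 -0.61), Acad11 (0.56) and 4930453N24Rik (-1.46). The brightest probe sets of these genes differed by -0.18, 0.21 and 0.17 (adjusted p = 0.433, 0.281 and 0.495), the last opposite in sign. Ran, a GTPase of nuclear transport, was 1.51-fold lower on 1 such probe set (adjusted p = 0.037), but its brightest probe set differed by -0.18 (adjusted p = 0.383). Rab27a, a GTPase of secretory granules, was 1.84-fold higher on 1 probe set (adjusted p = 0.04), and Acp1 1.98-fold lower on 1 (adjusted p = 0.0304). The brightest probe set differed by 0.49 for Rab27a (adjusted p = 0.437) and by -0.10 for Acp1 (adjusted p = 0.634). Rabepk was 0.59 higher on 1 probe set (adjusted p = 0.0369), yet another of its probe sets differed by -0.60 (adjusted p = 0.119). Nnt, the mitochondrial transhydrogenase, differed by 1.40 (adjusted p = 0.0587) and 1.04 (adjusted p = 0.148) on its 2 bright probe sets. Chil1, a chitinase-like protein, differed by 2.11 (SE 0.40, adjusted p = 0.143). Nnt and Chil1 did not pass.

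Chance assignment of samples was examined over the 35 splits of the 8 samples into 4 and 4. Only 1 split, the real one, called as many as 37 probe sets, and the highest count in any other was 0. This argues against chance for the probe set count. It cannot exclude chance, since 1 of 35 is the smallest share the comparison can give. As many lists as the real 5 were called in 17 of the 35 splits, and the highest other count was 14, so chance cannot be excluded for the list count. These counts hold at camera's preset correlation of 0.01, whereas the estimated correlation was 0.388 for ribosomal protein and 0.641 for cell cycle genes, and a structure among the samples was not tested apart from it.

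Called genes lay beside Pik3cd in gene order (odds ratio 25.8), in both directions. Of these 6 neighbours, 6 were still called after cyclic loess, which removes only a smooth signal-dependent difference between arrays. Such a difference was small here, with a median log2 difference between -0.09 and 0.13 across bins of mean signal. The neighbours differed by more, the smallest in size being -0.94 (Znf41-ps), so their calls could hardly be lost. A smooth difference of this kind is too small to account for them. Other differences between arrays were not tested by cyclic loess and stay open. DNA of another strain carried along with the targeted allele may account for the cluster, a hypothesis found and tested on the same data. Probe sets of Zfp991 moved in opposite directions, both past the threshold. This is not particular to the cluster. On other chromosomes, Rabepk (0.59 and -0.60) and Wdfy1 (1.97 and -0.37) had such probe sets too, with the lower one short of the threshold. Whether further strain segments exist could not be told from the other called genes, whose neighbouring pairs (Scrn2 with Gsdma2, Rab6b with Acad11) had a permutation p of 0.0807. Loss of p110δ itself stays open and untested for these genes. So does a difference between chimeric and other mice, since only the p110d-/- titles hold the word chimeric. No strain background is known for these samples.

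The ribosomal protein (-0.20) and oxidative phosphorylation (-0.17) lists were lower and the PI3K signalling list (0.17) higher. After removal of a trend with genomic span the means were -0.13, -0.14 and 0.15, past camera's threshold at the preset correlation but not with an estimated one (adjusted p = 0.756, 0.756 and 0.729). The removal left 65.7%, 81.5% and 86.8% of the differences. It was fitted over all probe sets with a known span, dim ones included. Spearman rho across genes was higher above the median signal (0.30) than over all genes (0.232). Most members lie above that median (28 of 29, 33 of 33 and 33 of 35), so the fit may correct them too little. The percentages left thus cannot decide whether the trend is the whole cause. A signal-dependent difference between arrays is argued against for ribosomal proteins (-0.21 after cyclic loess) and oxidative phosphorylation (-0.22). Lists matched on signal had positive medians there (0.02 and 0.07). Neither list passed after cyclic loess with an estimated correlation (camera adjusted p = 0.657 for each). Such a difference stays open for PI3K signalling, where lists matched on signal had a median of 0.09 (the list lay at percentile 98.9 of them). After cyclic loess the PI3K signalling mean fell to 0.11 and the call at the preset correlation ended (camera adjusted p = 0.115). Chance stays open for ribosomal proteins and oxidative phosphorylation, whose groups overlapped before and after these corrections (exact permutation p = 0.114 and 0.0857 before). It stays open for PI3K signalling too. The groups of that list did not overlap before correction (exact permutation p = 0.0286, the smallest possible) but did after cyclic loess (0.0857). An effect of p110δ loss is open and untested for the 3 lists.

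T cell (-0.20) and B and plasma cell (-0.25) genes were lower in p110d-/- samples at camera's preset correlation (adjusted p = 0.579 with an estimated correlation for each), the latter by -0.14 without Jchain. After cyclic loess the means were -0.17 and -0.21 and neither list passed (adjusted p = 0.115 and 0.22), so a signal-dependent difference between arrays stays open. Fewer T cells among the sorted cells may account for the T cell list, whose median lay at percentile 0.15 of lists matched on signal, but the alternative activation (0) and MHC class II (0.1) lists lay as low, and without WT 4 the mean was -0.10 (adjusted p = 0.18). Fewer B or plasma cells stay open at percentile 2.55, with Ighm at 7.74 in WT and 7.18 in p110d-/- and Bank1, the most abundant, at 10.49 and 10.52. The sort for CD11b, CD115 and F4/80 without CD19 would remove such cells, 2 of the 17 T cell genes (most abundant Zap70, 9.04 and 8.81) also stand in other lists, and a biological difference in tumour lymphocytes was not tested.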
